A study of Marchantia polymorpha with 4 samples.

How the data were processed

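The series holds 4 two-colour Agilent arrays of the liverwort Marchantia polymorpha. Each array compared RNA of the Mpfad5 mutant with RNA of Tak-1, the male laboratory accession that served as its control. Per the labels' protocols, plants were grown for 3 weeks on Gamborg's B5 medium at a strength of 0.5 with 1% agar. The treatment protocol has the tissue injured with tweezers and frozen after 90 min, with no difference between genotypes. The wound tag, however, is repeated on the Tak-1 channel and not on the Mpfad5 channel, which was taken as a slip, so the wounding of Mpfad5 rests on the protocol alone. Apical fragments without gemma cups were ground. An independent biological replicate held 6 to 8 plants, and 200 ng of total RNA was amplified and labelled. The labels put Mpfad5 on Cy3 and Tak-1 on Cy5 on all 4 arrays, so that no array had its dyes swapped and the effect of the genotype cannot be separated from a dye effect of single probes. They do not say whether each array had its own Tak-1 RNA. They name a single mutant, while the names of the deposited scans carry 2 mutant designations, one on replicates 1 and 2 and another on replicates 3 and 4. Groups were taken from the labels alone, so the 4 replicates may hold 2 mutant lines. The arrays shared a slide and a scan, so that no batch could be fitted.

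Per the file headers, the spots were read with scanner G2505C and quantified with Agilent Feature Extraction 10.7.3.1, protocol GE2_107_Sep09, on array design 084032. The deposited spot values used here are mean intensity and median local background in each channel, on a linear scale and not normalised. The deposited flags for outlier, saturated and well-above-background spots were used as given. The deposited log10 ratio column of the scanner software, which is background-subtracted and dye-normalised by it, and the deposited value table served as alternatives. The scale of the value table is not given in the sources used here. Set against the scanner values, these deposited log2 values, as the authors made them, followed log2(Cy3/Cy5) after loess with no background correction, with correlations across spots of 0.966 to 0.992 and slopes of 1.02 to 1.21. Its column medians were 0, 0.01, 0.01 and 0 for replicates 1 to 4, and how the submitters made it remains unknown. Its direction is that of the labels' dyes. The 350 two-colour spike-in spots gave no check of the dyes, since 3 to 10 of them were well above background in Cy3 and 9 to 19 in Cy5.

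Intensities were corrected with normexp (offset 50) and normalised within each array by loess in limma 3.58.1 under R 4.3.3, with control spots and outlier spots at weight 0. Control and outlier spots were then left out, 59 to 75 outlier spots per array. No spot was saturated. Ratios are log2(Cy3/Cy5), Mpfad5 over Tak-1. Spots of a probe were averaged, then probes of a gene, a gene being the locus identifier without its transcript suffix. A probe was kept when it was well above background in at least 1 channel on at least 3 of the 4 arrays, which left 16055 of 40422 probes and 8658 of 19217 genes. Between 32.4% and 45.1% of spots were well above background in Cy3 and between 29.4% and 39.1% in Cy5. The number of arrays limits the precision. A gene with no probe well above background in a channel on any array is named as such, and its ratio stays open to dye bias. Raising its signal there to the lowest signal above background, after loess and Aquantile, changed the fold of no such named gene. Their ratios are therefore means and not lower bounds.

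Each gene's mean log2 ratio was tested against 0 with lmFit and eBayes over the 4 arrays, which pairs the RNAs that shared an array, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Gene lists were fixed by words in the annotation before the data were examined, and tested from 5 members upward with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. After the annotation, but not the intensities, had been read, members matched inside other words or of another function were removed by a written list of exclusions; the lists as first written are an alternative. The list of polyphenol oxidases and tyrosinases matched no gene. Names are those the array annotation gives for the best Arabidopsis match, which 7391 of the 8658 tested genes have; they name a related sequence and not a proven function. The identifiers matched 0 entries of the RefSeq gene table for assembly MpTak2_v7.1, and no genome coordinates were used. The rule for named genes was fixed before the data were examined. It takes the 12 highest and 12 lowest log2 ratios among genes past the threshold with the same sign on all 4 arrays. It adds the 3 members with the smallest p of the lists for jasmonate biosynthesis, jasmonate signalling and desaturases, and of each list past camera's threshold or with at least 5 members past the gene threshold. It always takes the targeted gene.

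The fit was tested on simulated data: intensities with the real backgrounds, levels and gene spreads, an intensity-dependent dye trend, and 200 changed genes among 8658. Of 50 genes raised by a log2 of 1, 82% were recovered, and of 50 lowered by as much, 86%. At a log2 of 0.5 the shares were 24% for raised and 46% for lowered genes. Unchanged genes made up 1.65% of the calls, and with no gene changed there were 0 calls. Noise was drawn independently between genes and arrays, without a dye effect of single probes or a shared RNA. These shares therefore do not measure false calls from such causes. They also hold for 200 changed genes, fewer than the 2618 called in the real data. Alternatives covered the offset, no background correction, median centring, the scanner's own log ratio, the deposited value table, Aquantile, the filter, the probes of a gene, a trended robust eBayes, channels as unpaired samples, and each replicate left out. A trend with probe base composition, the lists as first written and averaging over genes with the same Arabidopsis match were added after the data had been seen.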

Results

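The data were 4 direct two-colour hybridisations of wounded Mpfad5 against wounded Tak-1 plants of Marchantia polymorpha, replicates 1 to 4, frozen 90 min after wounding. The mutant is named for FAD5, a plastid fatty acid desaturase. The comparison asks which transcripts differed between the genotypes in wounded tissue. That both genotypes were wounded rests on the treatment protocol in the labels, since the wound tag is repeated on the Tak-1 channel and not on the Mpfad5 channel; if the Mpfad5 plants were not wounded, every ratio would also hold the response to wounding. By the protocol, no unwounded plants were compared, so the response to wounding itself was not measured. Spots well above background numbered 23235, 19444, 24832 and 27134 in the mutant channel and 23529, 17695, 21928 and 22619 in the control channel for replicates 1 to 4. Values are mean log2 ratios of Mpfad5 over Tak-1 ± SD over the 4 arrays (n = 4), and p-values are Benjamini-Hochberg adjusted p-values from limma unless a set test is named.

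The targeted gene was read first. FAD5 (Mapoly0037s0130) had log2 ratios of 0.16 on replicate 1 and 0.04 on replicate 2, and of -3.56 and -3.62 on replicates 3 and 4. The mutant channel was thus 11.8-fold and 12.3-fold lower than the control channel on replicates 3 and 4, and close to it on replicates 1 and 2. The mean was -1.74 ± 2.13 (adjusted p = 0.126), so the change over all 4 arrays was not larger than the spread between them. The gene was well above background in both channels of every array. The labels name a single mutant, Mpfad5, for all 4 arrays, but the names of the deposited scans carry 2 mutant designations, one on replicates 1 and 2 and another on replicates 3 and 4, the same division as the FAD5 values. The labels do not record these designations, so the arrays were not divided by them, and this mean and SD, like every n = 4 here, may pool 2 mutant lines. A mutant can keep its mRNA, so the level on replicates 1 and 2 neither bears out nor contradicts the labels there. Directions below follow the dyes in the labels.

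**Figure D1:**
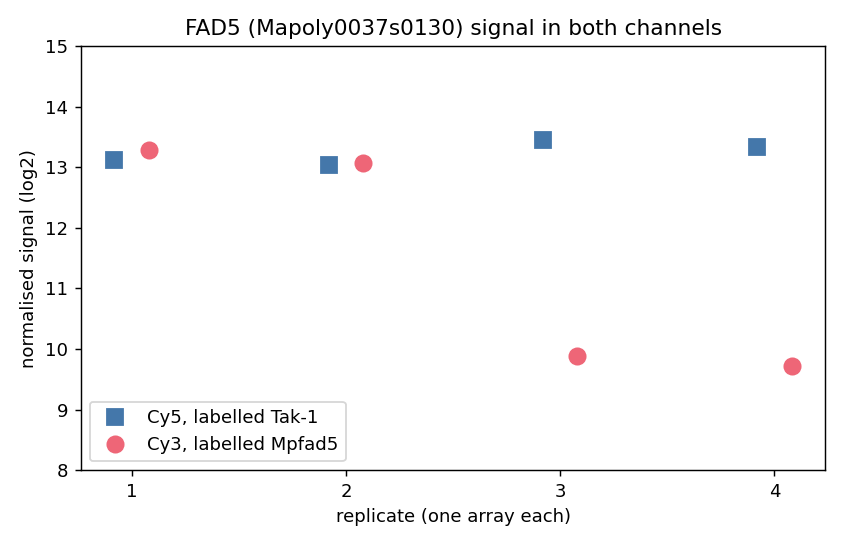
Normalised log2 signal of FAD5 (y axis) on each of the 4 arrays (x axis), with squares for the channel labelled Tak-1 and circles for the channel labelled Mpfad5. The control channel lies between 13.03 and 13.44 on all arrays, and the mutant channel drops to 9.88 and 9.72 on replicates 3 and 4.

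Across the transcriptome, 2618 of 8658 tested genes (30.2%) passed the threshold, 1518 higher and 1100 lower in Mpfad5. Most changes were small, with a median of 1.35-fold. At least 2-fold changes were found for 211 genes, 83 higher and 128 lower, and 210 of these had the same sign on all 4 arrays. Log2 ratios correlated across genes, which are not independent replicates, at r = 0.51 to 0.76 between arrays. The lowest values were those of replicates 1 and 2 (0.51), which share a scan designation, and of 1 and 4 (0.51). Replicates 3 and 4 gave 0.76, 1 and 3 0.74, 2 and 4 0.73, and 2 and 3 0.68. The p-values take the 4 arrays as independent, which was not checked and would not hold if arrays shared a Tak-1 RNA. Without replicate 3 the count fell to 767 and without replicate 4 to 1252; channels treated as unpaired samples gave 799 genes. Median centring in place of loess gave 1072 genes, 775 higher and 297 lower, and turned the 2-fold split to 132 higher and 79 lower; the scanner's own log ratio gave 523 genes at 2-fold, 297 higher and 226 lower.

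**Figure D2:**
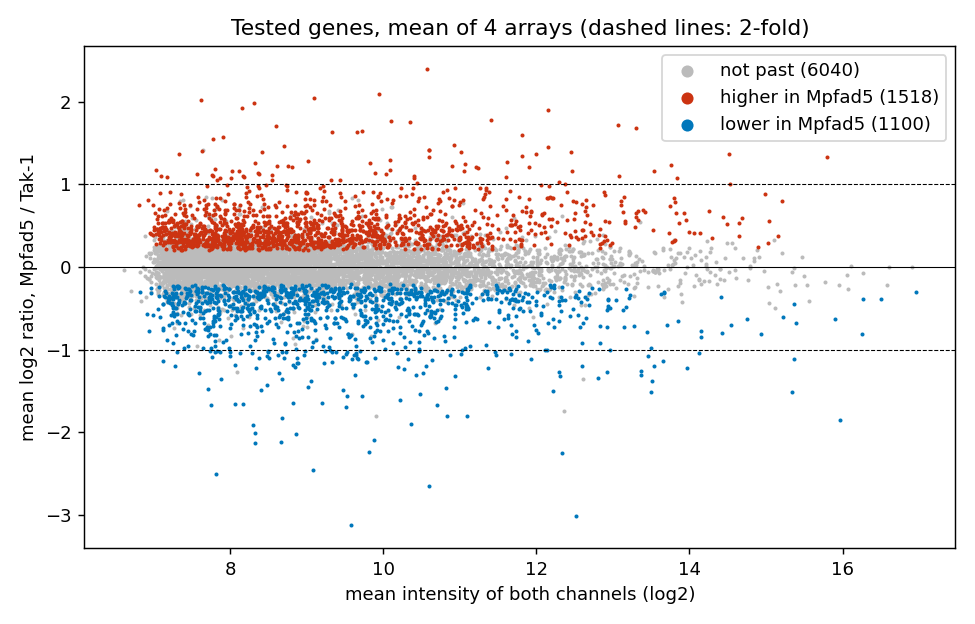
Mean log2 ratio of Mpfad5 over Tak-1 (y axis) against mean log2 intensity (x axis) for the 8658 tested genes. Red points are the 1518 genes called higher, blue points the 1100 called lower, and dashed lines mark 2-fold.

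The lowest ratio was that of Mapoly0038s0025, whose match is the gibberellic acid methyltransferase GAMT2, at -3.13 ± 0.34 (adjusted p = 0.00102), an 8.74-fold difference. Malate synthase (Mapoly0154s0035), an enzyme of the glyoxylate cycle, followed at -3.02 ± 0.53. Among the 12 lowest genes were GDSL-like lipases Mapoly0048s0056 (-2.50 ± 0.45, probes at -2.11 and -2.89) and Mapoly0127s0004 (-2.46 ± 0.70). Mapoly0048s0056 was not well above background in the mutant channel on any array, which leaves its 5.66-fold difference uncertain. A peroxidase (Mapoly0008s0232) was at -2.13 ± 0.31, a mean of probes at -1.44 and -2.82. The same group held 4 genes of the thaumatin and PR5 type, proteins that accumulate in pathogen-challenged plants. These were Mapoly0002s0336 (-2.25 ± 1.24), Mapoly0097s0013 (-2.12 ± 0.46), Mapoly0097s0008 (-2.01 ± 0.49) and Mapoly0097s0012 (-2.01 ± 0.51). The last 3 carry nearby numbers on a scaffold, and their probes were not checked for shared sequence. Genes with no listed match were Mapoly0062s0122 (-2.66 ± 0.44), Mapoly0030s0002 (-2.24 ± 0.20) and Mapoly0062s0058 (-2.09 ± 0.35). Mapoly0002s0336 lost its call without replicate 3 (adjusted p = 0.0721).

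At the other end, chlorophyllase (Mapoly0008s0176), which removes the phytol tail of chlorophyll, was 5.28-fold higher (2.40 ± 0.52, adjusted p = 0.00222). The copper chaperone of superoxide dismutase CCS (Mapoly0152s0017) was 4.27-fold higher (2.09 ± 0.21, adjusted p = 0.00106). A Rubisco small subunit gene (Mapoly0114s0057) was at 1.90 ± 0.80. An NC domain protein (Mapoly0803s0001) reached 1.99 ± 0.38, a gene matched to the ECA1 gametogenesis family (Mapoly0130s0008) 1.78 ± 0.29, and a UPF0497 protein (Mapoly0159s0027) 1.72 ± 0.61. The other 6 of the 12 highest had no listed match. Mapoly0027s0161 was at 2.03 ± 0.65 (4.08-fold), an uncertain size since the control channel was not well above background on any array. Mapoly0189s0017 was at 2.05 ± 1.20, Mapoly0041s0063 at 1.93 ± 0.55, Mapoly0093s0052 at 1.77 ± 0.49, Mapoly0093s0051 at 1.76 ± 0.43 and Mapoly0054s0040 at 1.71 ± 0.68. Mapoly0189s0017 lost its call without replicate 3 (adjusted p = 0.0815).

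**Figure D3:**
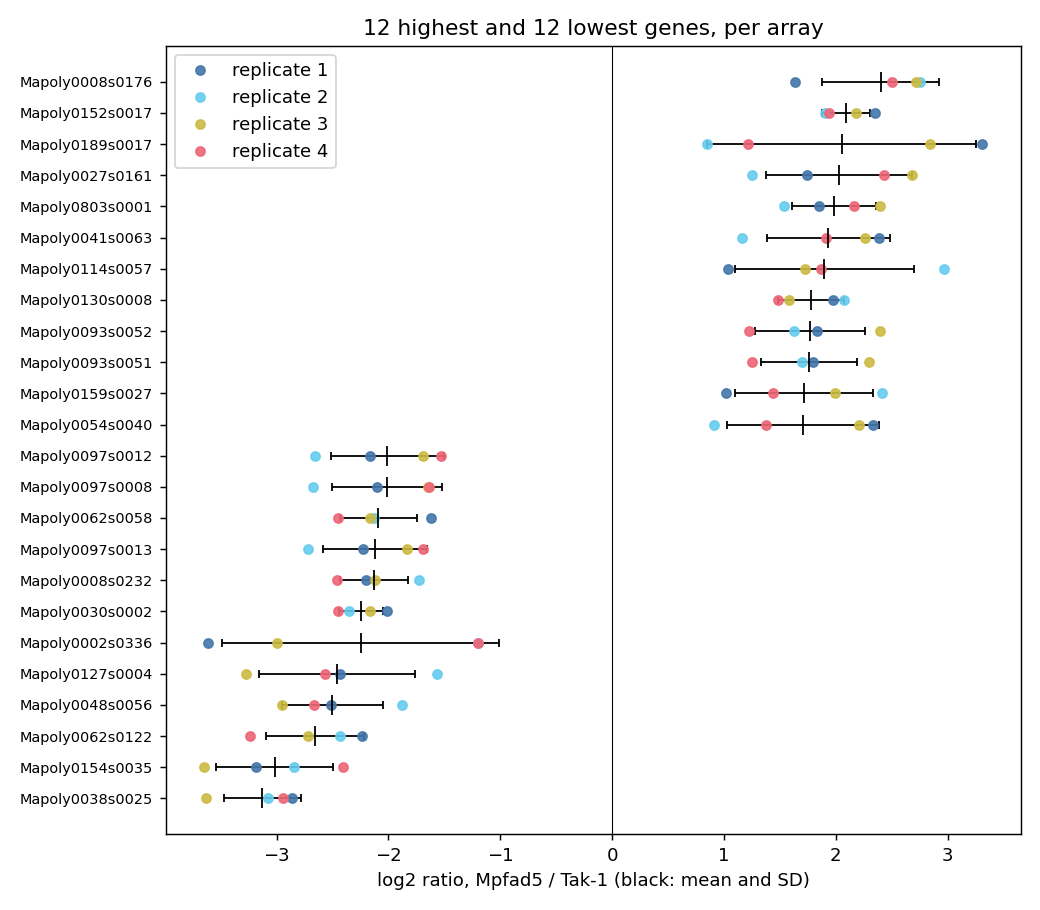
Log2 ratio of Mpfad5 over Tak-1 (x axis) for the 12 highest and 12 lowest genes (y axis), with a coloured point per replicate and the mean and SD in black. By the rule that chose these genes, all 4 points of each lie on the same side of 0. Mapoly0189s0017 and Mapoly0002s0336 spread most, with SDs of 1.20 and 1.24.

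Photosynthesis genes were higher in Mpfad5. Of 25 light-harvesting proteins, which bind the antenna chlorophylls, 16 rose, 4 fell and 5 did not pass, with a median log2 ratio of 0.57 (camera adjusted p = 0.00273 at the preset correlation; adjusted p = 0.859 with an estimated correlation). Adjusted over the list alone, 16 were higher and 5 lower. The smallest p-values belonged to LHCA3 (Mapoly0066s0050, 1.37 ± 0.15), LHCA2 (Mapoly0083s0003, 0.94 ± 0.11) and LHCB2 (Mapoly0057s0073, 1.60 ± 0.31). Of 61 genes of the photosystems and photosynthetic electron transport, 35 rose and 3 fell, with a median of 0.43 (camera adjusted p = 3.14e-06; adjusted p = 0.859 with an estimated correlation), and 38 and 6 passed adjusted over the list alone. The lists share 16 genes; the remaining 45 had 24 higher, 1 lower and a median of 0.41. In the Calvin cycle list, 10 of 18 genes rose and 0 fell, with a median of 0.52 (camera adjusted p = 0.00457; adjusted p = 0.859 with an estimated correlation), and 10 passed adjusted over the list alone. This list was mostly Rubisco small subunits, 15 genes of which 8 rose. They included Mapoly0114s0049 (1.33 ± 0.30), Mapoly0114s0051 (1.68 ± 0.50) and Mapoly0114s0055 (1.34 ± 0.49), neighbours of the gene named above, and with genes of the same Arabidopsis match averaged the Calvin cycle list no longer passed (adjusted p = 0.15). Of 3 tested genes for chlorophyll and tetrapyrrole synthesis, too few for a set test, 2 rose and 1 fell, also adjusted over the list alone.

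Defence proteins moved the other way. Of 104 tested, 46 fell, 12 rose and 46 did not pass, with a median of -0.39 (camera adjusted p = 3.14e-06; adjusted p = 0.859 with an estimated correlation). Adjusted over the list alone, 49 were lower and 13 higher. By its words the list takes in germin-like proteins matched to GLP10 (14 of 23 lower, 1 higher) and CAP proteins (10 of 16 lower, 1 higher). Many of its lower genes thus come from repeated families. With genes of the same Arabidopsis match averaged, 38 values remained and the list still passed camera (adjusted p = 0.002). Besides Mapoly0097s0013, the smallest p-values belonged to an osmotin (Mapoly0866s0001, -1.65 ± 0.27, probes at -1.03 and -2.27) and to a dirigent-like protein (Mapoly0152s0002) that was higher, at 1.26 ± 0.19. Among peroxidases, catalases and superoxide dismutases, 17 of 74 fell and 7 rose (median -0.09, camera adjusted p = 0.0145; adjusted p = 0.859 with an estimated correlation), and 19 and 7 passed adjusted over the list alone. Peroxidases Mapoly0076s0031 (-1.01 ± 0.16) and Mapoly0009s0083 (-0.84 ± 0.19) were among the lower ones. In phenylpropanoid and flavonoid synthesis, 8 of 38 fell and 4 rose, also adjusted over the list alone (median -0.18, camera adjusted p = 0.0201; adjusted p = 0.859 with an estimated correlation). Of 17 genes matched to chalcone and stilbene synthases, which include the enzyme that commits precursors to flavonoids, 5 fell and 0 rose (family test adjusted p = 0.607), among them Mapoly0009s0178 (-0.90 ± 0.29) and Mapoly0070s0036 (-0.78 ± 0.31), and cinnamate 4-hydroxylase (Mapoly0081s0009) was higher at 0.53 ± 0.18. The calls of these last 2 lists were lost under several alternatives, among them no filter on dim probes (adjusted p = 0.31 and 0.188).

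**Figure D4:**
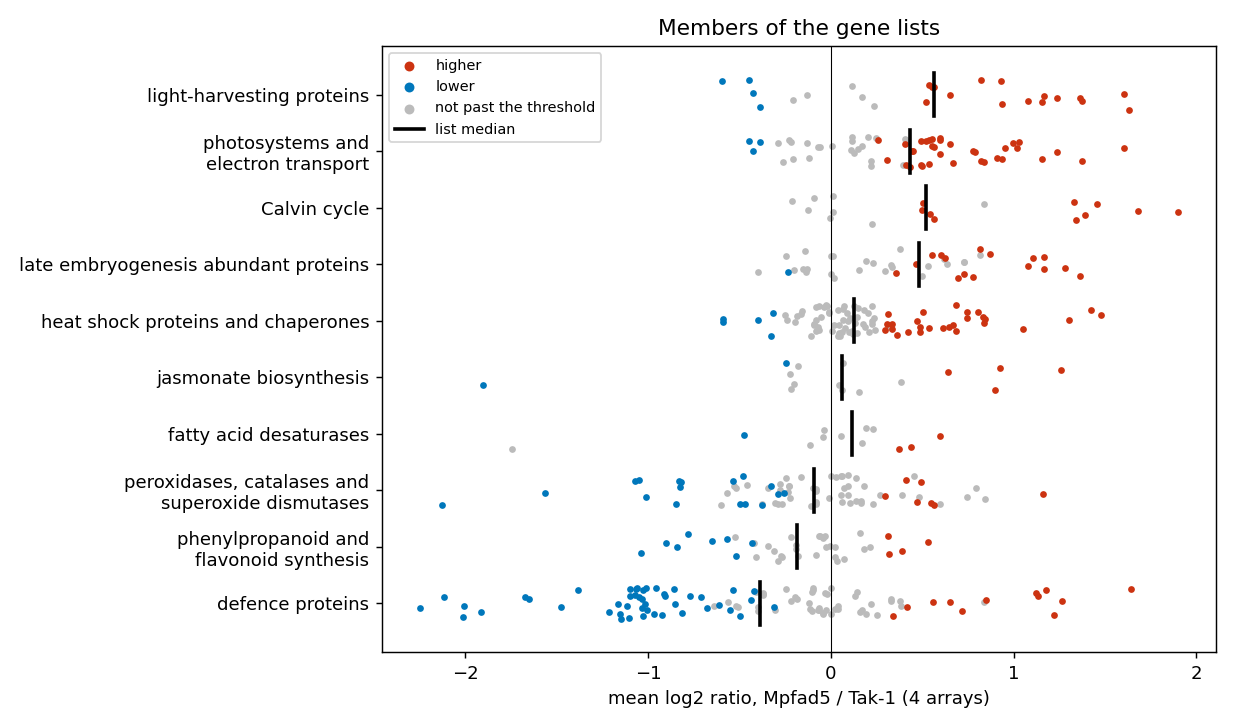
Mean log2 ratio of Mpfad5 over Tak-1 over 4 arrays (x axis) for the tested members of 10 gene lists (rows), with a point per gene, red for higher, blue for lower and grey for not past the threshold, and black bars at list medians. Medians run from 0.57 for light-harvesting proteins to -0.39 for defence proteins; vertical scatter within a row has no meaning.

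Of 88 heat shock proteins and chaperones, 27 rose and 5 fell, with a median of 0.12 (camera adjusted p = 0.00998; adjusted p = 0.859 with an estimated correlation), and 32 and 7 passed adjusted over the list alone. The small heat shock proteins HSP17.6A (Mapoly0010s0142, 1.48 ± 0.16), the plastid HSP21 (Mapoly0045s0146, 1.42 ± 0.19) and an HSP20-like chaperone (Mapoly0076s0005, 1.05 ± 0.11) led the list. Of 42 late embryogenesis abundant proteins, associated with desiccation tolerance, 16 rose and 1 fell, with a median of 0.48 (camera adjusted p = 0.00273; adjusted p = 0.859 with an estimated correlation), and 20 and 1 passed adjusted over the list alone. Members included Mapoly0006s0097 (0.81 ± 0.15), Mapoly0025s0038 (1.11 ± 0.26) and Mapoly0025s0040 (1.28 ± 0.36). With genes of the same Arabidopsis match averaged, both lists no longer passed (adjusted p = 0.126 for either), and late embryogenesis abundant proteins also lost their call when both channels had to be above background on all arrays (adjusted p = 0.146). No list passed with an estimated correlation, where the lowest unadjusted p was 0.0362, for defence proteins. The medians of the 8 lists that passed kept their sign under each scaling tried. Between arrays, that of peroxidases, catalases and superoxide dismutases turned, with 0.04 on replicate 1 and -0.25, -0.13 and -0.36 on replicates 2 to 4. For late embryogenesis abundant proteins it was 0.70, 0.38, 0.60 and 0.07 on replicates 1 to 4. Directional fry did not pass for the Calvin cycle (adjusted p = 0.0883), late embryogenesis abundant proteins (0.0814), peroxidases (0.215) and phenylpropanoids (0.232).

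Genes listed for jasmonate synthesis did not stand apart from other genes in camera, which was not run for signalling. Jasmonate is a wound hormone whose precursors are plastid fatty acids. Of 15 tested genes for jasmonate biosynthesis, 4 rose and 2 fell, with a median of 0.06 (camera adjusted p = 0.916; fry, which does not compare with other genes, adjusted p = 0.0139, higher, but 0.569 and lower with genes of the same Arabidopsis match averaged), and 5 and 3 passed adjusted over the list alone. Members of the list moved in opposite directions. Lipoxygenases Mapoly0420s0001 (1.26 ± 0.06) and Mapoly0006s0130 (0.92 ± 0.14), both matched to LOX1, were higher. Lipoxygenase Mapoly0106s0031, matched to a PLAT/LH2 domain lipoxygenase, was 3.75-fold lower (-1.91 ± 0.61). The list takes lipoxygenases by name, so these genes need not all act in jasmonate synthesis. For jasmonate signalling, 4 genes were tested, too few for a set test, with 1 higher and 1 lower, also adjusted over the list alone. The JAZ repressor gene Mapoly0097s0021 was at -0.32 ± 0.17 (adjusted p = 0.034), a call lost under 6 alternatives. A ZIM-like gene, MapolyY_B0021, was at 0.22 ± 0.04 (adjusted p = 0.0408), a call also lost under most of the replicate and normalisation alternatives. Its match is also named GATA24, and it need not act in jasmonate signalling. The TIFY8 match Mapoly0079s0053 was at -0.19 ± 0.14 (adjusted p = 0.105). Of 12 fatty acid desaturases, 3 rose and 1 fell (camera adjusted p = 0.835), and 4 and 1 passed adjusted over the list alone; the median was 0.11 and the mean, FAD5 included, -0.03. A fatty acid or sphingolipid desaturase (Mapoly0184s0017) was at 0.60 ± 0.16, FAD2 (Mapoly0075s0021) at 0.44 ± 0.04 and a stearoyl-ACP desaturase (Mapoly0246s0004) at -0.47 ± 0.17.

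In fatty acid synthesis, 5 of 18 genes rose and 6 fell (camera adjusted p = 0.835), and 6 and 6 passed adjusted over the list alone. With median centring in place of loess, 0 of them rose and 2 fell. Ketoacyl-CoA synthases of the KCS11 type, which elongate very long acyl chains, were lower (Mapoly0055s0027, -0.94 ± 0.09, and Mapoly0055s0025, -0.70 ± 0.13), as was an acetyl-CoA carboxylase subunit (Mapoly0068s0003, -0.88 ± 0.39). Of 61 lipases and patatins, 12 rose and 12 fell (camera adjusted p = 0.835), and 13 and 13 passed adjusted over the list alone; a further GDSL-like lipase, Mapoly0076s0069, was at -0.79 ± 0.18. In both lists the median was above 0 (0.03 and 0.02) and the mean below it (-0.09 and -0.07).

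Among the other lists, none of which passed camera, counts of higher and lower genes were as follows. For lectins, 5 of 20 rose and 0 fell, with Mapoly0012s0025 at 1.11 ± 0.28, Mapoly0150s0020 at 0.38 ± 0.10 and Mapoly0026s0080 at 0.41 ± 0.16. Mapoly0026s0080 was not well above background in the control channel on any array. For glutathione S-transferases, 3 of 23 rose and 3 fell, with Mapoly0031s0032 at -0.83 ± 0.22, Mapoly0020s0134 at -0.73 ± 0.26 and Mapoly0193s0023 at 0.97 ± 0.42. For cytochrome P450 genes, 12 of 54 rose and 9 fell, with Mapoly0022s0193 at 0.76 ± 0.20, Mapoly0010s0184 at -0.61 ± 0.14 and Mapoly0011s0066 at 0.49 ± 0.11. For nitrate and ammonium use, 5 of 14 rose and 1 fell, with nitrate reductase (Mapoly0023s0052) at 1.10 ± 0.38 (probes at 0.79 and 1.41). The nitrate transporter match NRT2.1 (Mapoly0020s0038), not well above background in the control channel on any array, was at 0.63 ± 0.15. The molybdenum cofactor gene CNX7 (Mapoly0053s0105) was at -0.61 ± 0.07. For cell wall genes, 5 of 45 rose and 9 fell, with expansin EXPA1 (Mapoly0061s0098) at 0.51 ± 0.07, XEG113 (Mapoly0019s0126) at 0.55 ± 0.11 and XTH7 (Mapoly0040s0065) at -0.60 ± 0.15. For ABC transporters, 5 of 19 rose and 1 fell, with Mapoly0087s0041 at 0.40 ± 0.06, Mapoly0094s0070 at 0.55 ± 0.19 and Mapoly0142s0030 at 0.37 ± 0.11.

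Of 28 bHLH factors, 8 fell and 3 rose, with Mapoly0025s0044 at -0.62 ± 0.15, Mapoly0040s0112 at -0.55 ± 0.25 and Mapoly0037s0007 at 0.59 ± 0.22. Of 119 receptor-like kinases, 21 fell and 13 rose, with Mapoly0020s0097 at -0.59 ± 0.13, Mapoly0031s0071 at -0.58 ± 0.14 and Mapoly0131s0002 at 0.69 ± 0.24. Of 34 cell division genes, 7 rose and 2 fell, with histone H2A (Mapoly0007s0226) at 0.59 ± 0.17, POK2 (Mapoly0029s0045) at -0.50 ± 0.20 and RCY1 (Mapoly0037s0071) at -0.34 ± 0.07, whose probes disagreed and whose brightest probe was at 0.01. Of 21 cytosolic ribosomal proteins, 5 rose and 2 fell, with Mapoly0078s0013 at 0.75 ± 0.24, Mapoly0122s0034 at 0.46 ± 0.10 and Mapoly0020s0151 at 0.43 ± 0.13. WRKY factors had 3 higher and 1 lower of 12, MYB factors 2 and 2 of 17, AP2/ERF factors 1 and 0 of 5, terpene synthesis genes 0 and 1 of 9, and genes of sperm and antheridia 1 and 1 of 4. Adjusted over the list alone, the counts of higher and lower genes were 6 and 4 for lectins, 3 and 3 for glutathione S-transferases, 13 and 9 for cytochrome P450 genes, 5 and 5 for nitrate and ammonium use, 5 and 9 for cell wall genes, and 5 and 1 for ABC transporters. They were 4 and 8 for bHLH factors, 13 and 20 for receptor-like kinases, 3 and 2 for cell division genes, 5 and 2 for ribosomal proteins, 3 and 1 for WRKY, 2 and 4 for MYB and 1 and 0 for AP2/ERF factors, 0 and 1 for terpene synthesis, and 1 and 1 for sperm and antheridia. Median centring in place of loess turned or evened the balance of calls in several lists. It gave 1 higher and 0 lower for bHLH factors, 9 and 3 for receptor-like kinases, 6 and 4 for cell wall genes, and 1 and 1 for ABC transporters; relative to the median of all genes, the medians of bHLH factors (-0.04) and receptor-like kinases (-0.08) stayed lower. The median, the mean and the direction of camera differed in sign for glutathione S-transferases, MYB factors, cell wall genes, nitrate and ammonium use and the lipid lists named above, none of which passed. In fry, which asks whether a list's genes moved one way on balance, directional adjusted p-values under the threshold were found for heat shock proteins (0.0139), jasmonate biosynthesis (0.0139, higher), defence proteins (0.0163), ABC transporters (0.0163), bHLH factors (0.0181), light-harvesting proteins (0.0213), photosystems (0.0213) and ribosomal proteins (0.0213). None of these 8 calls held with median centring (lowest adjusted p = 0.584, bHLH factors turned to higher) or without replicate 4 (lowest adjusted p = 0.0653). Without replicate 3 the call of jasmonate biosynthesis alone held (adjusted p = 0.0112), without replicate 2 there were 4 calls left and with channels unpaired 3. With genes of the same Arabidopsis match averaged, 6 held, and those of jasmonate biosynthesis (adjusted p = 0.569, lower) and defence proteins (adjusted p = 0.0564) were lost.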

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

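The tests of FAD5, base composition, intensity and probe families were chosen after the patterns they address had been seen. Of 117 sets of 4 values examined (named genes, list medians and array measures), 4 had a replicate far from the others, where chance gives about 1 in 20. Lipoxygenase Mapoly0106s0031 was at -1.0 on replicate 2 and between -2.09 and -2.29 on the others. On replicate 3, the ZIM-like gene MapolyY_B0021 was at 0.27 against 0.19 to 0.20, XTH7 (Mapoly0040s0065) at -0.37 against -0.66 to -0.70, and the median of bHLH factors at 0.0098 against -0.07 to -0.09.

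FAD5 was 11.8-fold and 12.3-fold lower in the mutant channel on replicates 3 and 4 and near the control on replicates 1 and 2. A faulty probe is argued against by the probes of the gene, which differed by at most 0.14 log2 units on replicates 3 and 4. An exchange of dyes or labels on replicates 1 and 2, or an absence of mutant RNA there, stays open. The highest log2 ratio of FAD5 was 0.16, but after an exchange it would also be near 0 in a line that keeps this mRNA, and the other genes' ratios correlated at 0.51 or more between every pair of arrays, but a dye effect shared by all arrays would give the same value. A candidate explanation that also stays open is the use of 2 mutant lines, of which one keeps its FAD5 mRNA: the names of the deposited scans carry a designation for replicates 1 and 2 and another for replicates 3 and 4. It was not tested, because the labels name a single mutant and give no groups to compare.

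Photosynthesis lists were higher and defence proteins lower. A dye response that follows probe base composition explained 0.145% to 1.26% of the variance per array, and the smallest share of a list's shift left after its removal was 1.00, which argues against it. An intensity-dependent dye bias is argued against by 10000 random lists matched on mean intensity. All 4 lists (light-harvesting, photosystems, Calvin cycle and defence) lay outside their central range, which left out 0.5% of lists at either end. The draws took genes as unrelated, while the estimated correlation within the Calvin cycle list was 0.72. The range is therefore too narrow to test the lists themselves, and speaks to intensity alone. One probe family counted many times stays open in part: with genes of the same Arabidopsis match averaged, 3 of the 4 lists passed camera and the Calvin cycle did not. A dye effect of single genes cannot be told apart from the genotype, since 0 arrays had swapped dyes. The genotype stays open as well. So does a wounding of Tak-1 alone, since the wounding of Mpfad5 rests on the protocol.

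The 4 arrays can be turned against each other in 8 ways, too few for a share under 0.05. The real orientation, 1 of the 8, gave 2618 genes, 211 genes at 2-fold and 8 lists, and the highest of the others gave 0, 0 and 6. The other orientations thus gave 1 to 6 lists while 0 genes passed. Turning 1 array leaves part of a shared effect, but with 2 of the 4 turned there were still 1 to 4 lists. Camera at the preset correlation therefore passed lists where no gene passed, and its calls are weak evidence on their own. The 0 genes lend no weight to the gene counts. Turning arrays that share an effect, of genotype or dye, widens each gene's spread, so few calls could follow.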

How the results depend on the processing

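Base composition, the lists as first written and averaging over Arabidopsis matches were alternatives chosen after seeing the data. Of the counts, genes past the threshold numbered 1072 with median centring in place of loess and 799 with no replicate block (channels unpaired), and genes at 2-fold numbered 523 with the scanner's own log ratio; the cause was not tested. The gene lists fell from 8 to 3 with genes of the same Arabidopsis match averaged, where fewer values entered each list; light-harvesting proteins, photosystems and defence proteins still passed. Leaving out a replicate gave 767 (without replicate 3) to 2328 genes (1252 without replicate 4), and 155 to 225 at 2-fold; fewer arrays entered. Of the 2618 genes, 764 also passed without replicate 3 and 980 with median centring, and no call changed sign under either. The targeted gene FAD5 passed only with median centring (-1.62, adjusted p = 8.56e-13), where eBayes gave every gene the same variance (prior degrees of freedom Inf, 3.08 with loess) and so ignored the spread of this gene. Median centring moved the median of all genes by 0.11 log2 units to 0.14; relative to that median, light-harvesting proteins were at 0.52 and defence proteins at -0.45. Among named genes and camera's directions for the 8 lists it called, the only reversed value was that of Mapoly0037s0071 with the brightest probe (0.0052, adjusted p = 0.98); of all 2618 called genes, at most 4 changed sign under an alternative (no filter on dim probes). Among these genes and the camera calls of these lists, 22 calls were lost with no replicate block, 17 with median centring and 13 without replicate 3, all with the direction kept. Aquantile moves no ratio and is no check. Unfiltered, 2594 of 19217 genes passed. Dim probes limit the data: at most 45.1% of spots were well above background in a channel.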

Other observations

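Tests in this part were all chosen after the data had been seen. Families of at least 5 tested genes with the same annotated description (196 families, 392 one-sided Fisher's exact tests on 6739 genes, Benjamini-Hochberg adjusted) showed 6 families past the threshold. Germin-like proteins matched to GLP10 were lower in 14 of 23 genes and higher in 1 (median -0.97, adjusted p = 1.91e-05). RmlC-like cupins, a superfamily that takes in germins, were lower in 8 of 10 (median -0.97, adjusted p = 0.000371). No fixed list held the genes under this cupin description, but their result may not be separate from that of the germin-like proteins. CAP proteins, the family of PR1, were lower in 10 of 16 and higher in 1 (median -0.55, adjusted p = 0.00041). Higher were 5 of 5 genes matched to HSP17.6A (median 0.84, adjusted p = 0.0197), 20 of 53 transducin/WD40 proteins, with 4 lower (median 0.17, adjusted p = 0.0478), and 6 of 8 DUF1399 proteins (median 0.69, adjusted p = 0.0478). The germin-like, CAP and HSP17.6A families belong to the fixed defence and heat shock lists, so their results restate part of those lists. All 6 medians kept their sign under each scaling tried. The enrichment of transducin/WD40 proteins was lost with median centring (3 higher, 1 lower), with no background correction (14 higher, adjusted p = 0.622) and with the deposited value table (18 higher, adjusted p = 0.125), and that of DUF1399 proteins with the scanner's own log ratio (5 higher, adjusted p = 0.195). Genes of a family can share probe signal, so that these tests may count the same signal more than once. Averaging over genes of the same match was run for the fixed lists alone, so it does not check this for the families.

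Genes that carry neighbouring numbers on a scaffold changed together. Pairs were tested genes that follow each other directly among the tested genes of a scaffold, at most 2 numbers apart. Among 5950 such pairs, 30 had both genes changed at least 2-fold in the same direction, and 0 in opposite directions. Over 10000 shuffles of the calls the mean was 1.83 pairs and the highest 9 (permutation p = 1e-04, the smallest they can give), which argues against a chance order of genes. Of the 30 pairs, 12 shared an annotated family, 14 included a gene with no listed match, and 4 had matches of different families, no more than the upper bound of the shuffles for such pairs (4). Near-identical copies that share probe signal may therefore account for part of the pairs, and cannot be told apart from shared regulation of neighbours, because the family is unknown for the 14 pairs that include a gene with no listed match. A pair of different families, named after its values were seen, joined malate synthase Mapoly0154s0035 (-3.02) with Mapoly0154s0036 (-1.10), whose match is isovaleryl-CoA dehydrogenase, an enzyme of leucine breakdown.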
